A study of Mus musculus with 10 samples.

How the data were processed

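Messenger RNA was sequenced from the hippocampus of C57BL/6 mice aged 3 months, as 5 biological replicates without the thyroid-stimulating hormone receptor (Tshr-/-) and 5 of wild type, per the labels. The labels do not state whether a replicate is a single mouse, whether littermates were compared or whether the mutant mice, which lack the main signal for thyroid hormone synthesis, received thyroid hormone. The libraries were made with a kit that does not mark the strand, per the labels' protocols, so that reads of a gene and of a gene on the opposite strand cannot be told apart. Reads were aligned with HISAT2 2.0.5 to mm10 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The authors deposited 1 table of FPKM values (fragments scaled for gene length and library size) for 52636 genes in the 10 libraries, with the length, coordinates and type of each gene. The annotation release was not given in the sources used here.

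FPKM times gene length was a whole multiple of 1 step per library for 100% of the values above 0, within a tolerance of 0.01 of a read, and these multiples were taken as read numbers. They sum to 23899650 to 33529811 reads per library. Summed over all genes, FPKM times length came to between 0.945 and 1.06 times what a division by these reads alone would give. The library sizes that the authors divided by were therefore not exactly the reads in these rows, and how they were set is not given in the sources used here.

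The test of each gene was made on log2(FPKM + 0.1) in R 4.3.3 with limma 3.58.1, a model of the 2 genotypes with empirical Bayes moderation and a mean-variance trend, for the 15471 genes with a mean FPKM of at least 0.5 over all libraries. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p below 0.05. Differences are Tshr-/- minus wild type on the log2(FPKM + 0.1) scale, which understates the change of genes with low values. Gene lists for thyroid hormone action, synapses, signalling, stress, immunity, metabolism, cell types, hippocampal subfields and neighbouring tissue were fixed before the data were examined. Of the 43 lists, 42 had 5 or more measured genes and were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Beside it stand camera with a correlation estimated for each list, and fry, whose p-value tests whether the genes of a list move on balance in one direction. Fry does not compare a list with other genes, and neither does its second p-value, for change in either direction. Counts within a list are given after adjustment over all genes and adjusted over the list alone. Tshr and the mean level of the choroid plexus list were compared with 2-sided exact permutation tests, which with 5 against 5 libraries cannot give a p below 0.00794. Called genes within 10 Mb of Tshr were counted against the rest of the genome with Fisher's exact test.

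Genes are named by a rule also fixed before the data were examined. It takes Tshr and the nearest 3 tested genes on each side, and the called genes in each direction up to 10. Where fewer than 3 were called in a direction it takes the 5 with the smallest p. In each list described it takes up to 4 members with the smallest p, and it takes Hr, Klf9, Dio2, Dio3, Nrgn and Mbp whatever their values. A few genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen, and this is said where it appears.

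Alternatives fixed before the data were examined were pseudocounts of 1 and 0.01, no filter on low values, a mean FPKM of at least 1, median-ratio scaling, quantile normalization, no variance trend, robust empirical Bayes (statmod 1.5.0), array quality weights, protein-coding genes alone, the replicate number as a block, each library left out in turn, limma voom on the rebuilt reads, and windows of 5 Mb, 20 Mb and the whole chromosome. Chosen after seeing the data were a thalamus covariate, covariates for thalamus, choroid plexus and neocortex lists together, a comparison of the 6 libraries lowest in thalamic transcripts, an exact permutation test of list means, the choroid plexus mean over the same genes without Tshr-/- library 4, and a loess correction (span 0.4) of each library for GC content and gene length. GC content came from the GENCODE vM21 transcripts and covered 15434 of the 15471 genes. The steps were tested on simulated read numbers with the means and spread of these libraries, over 15304 genes in which known genes were changed. Of these, 18 of 49 genes changed 1.3-fold were called, 27 of 49 at 1.5-fold, 44 of 50 at 2-fold and 45 of 48 at 3-fold, with 6 unchanged genes among the 140 called. Each gene was drawn independently, without the variation that genes of neighbouring tissue share.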

Results

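Transcript levels were measured in the hippocampus of mice lacking Tshr, the receptor through which thyroid-stimulating hormone drives the thyroid gland, and of wild-type mice, in a study of spatial learning and memory. Each genotype had 5 libraries at 1 age of 3 months, so the series holds a single comparison. Means are given with the SD over the 5 libraries of a genotype throughout. The rebuilt reads per library ran from 25744854 to 28332278 in Tshr-/- and from 23899650 to 33529811 in wild type, a difference within the spread between libraries (exact permutation p = 0.651). The 2 genotypes also had similar shares of reads from mitochondrial genes, 3.89% ± 0.455 and 3.91% ± 0.374. In every library the Y-linked genes Ddx3y and Eif2s3y were expressed, at 7.84 to 11.3 and 8.37 to 12 FPKM, and Xist stayed at or below 0.0242 FPKM.

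Tshr itself (ENSMUSG00000020963, chromosome 12, 91384563 to 91549808 on the plus strand, mm10) was near the detection limit in both genotypes. It had 7 reads over the 5 Tshr-/- libraries and 32 over the 5 wild-type libraries. The Tshr-/- libraries 1, 2 and 3 had no Tshr read, which allows up to 0.0170, 0.0169 and 0.0190 FPKM at the level of 3 reads. Tshr-/- libraries 4 and 5 had 5 and 2 Tshr reads. The wild-type libraries 1 to 5 had 9, 12, 7, 2 and 2. Mean Tshr FPKM was 0.00861 ± 0.0136 in Tshr-/- and 0.0371 ± 0.0221 in wild type, a difference of -0.0285 with an exact permutation p of 0.0556. With Tshr-/- library 4 left out, the exact permutation p was 0.0317, and it was also 0.0317 without wild-type library 4 or 5. Without any other single library it was higher, from 0.0714 to 0.0794, and with the replicate number as a block it was 0.188. The median tested gene stood at 5.05 FPKM. The deleted part of the gene is not stated in the labels, so reads from elsewhere in Tshr check nothing, and intervals and limits for these reads cover counting error only.

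Libraries differed in markers of tissue next to the hippocampus. Ttr, the transthyretin made by choroid plexus, reached 2189 FPKM in Tshr-/- library 4 and lay between 0.830 and 84.1 FPKM in the other 9 libraries. The mean of the choroid plexus list was 1.01 higher in Tshr-/- on the log2 scale (exact permutation p = 0.349), and without Tshr-/- library 4 it was -0.03 (exact permutation p = 0.944) over the 4 genes that then passed the filter and 0.149 (0.698) over the same 13 genes. The thalamus and habenula list was higher in Tshr-/- libraries 1 and 2 and in wild-type libraries 2 and 5, by 1.42, 2.19, 0.66 and 1.26 above the mean of all libraries. In the 6 other libraries it lay from 0.48 to 1.32 below that mean. Zic1, a transcription factor of the thalamus and habenula, ranged from 1.49 to 31.1 FPKM. The first 3 principal components of the log values held 22.5%, 15.3% and 12.8% of the variance. The first set Tshr-/- libraries 1 and 2 (-28.3 and -38.1) against wild-type libraries 1, 3 and 4 (25.2, 22.5 and 25.3). The second set Tshr-/- library 4 (-45.2) and the third Tshr-/- library 5 (42.2) apart from the rest. Correlations between libraries had medians of 0.965 within Tshr-/-, 0.972 within wild type and 0.967 between the genotypes.

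Which transcripts of the hippocampus differ without Tshr was asked first gene by gene. Penk and Cyp26b1 fell in Tshr-/-, and no gene passed the threshold as raised. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819) encodes proenkephalin, the precursor of enkephalin opioid peptides. It went from 16.8 ± 1.87 FPKM in wild type to 9.22 ± 0.695 in Tshr-/-, a log2 difference of -0.85 ± 0.09 (SE, limma adjusted p = 0.0127). Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908) encodes an enzyme that breaks down retinoic acid. It went from 4.52 ± 0.796 to 1.57 ± 0.475 FPKM, a log2 difference of -1.49 ± 0.18 (SE, limma adjusted p = 0.0319). For both genes each Tshr-/- library lay below each wild-type library.

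Several genes lay just beyond the threshold, with 11 of them at adjusted p values from 0.05 to 0.051. Among genes lower in Tshr-/-, none of Kcns3, Akr1c18 and Calr passed. Kcns3, a modulatory potassium channel subunit, had 2.35 ± 0.225 FPKM against 3.43 ± 0.126. Akr1c18, a hydroxysteroid dehydrogenase, had 0.748 ± 0.256 against 2.04 ± 0.212. Calr, the endoplasmic reticulum chaperone calreticulin, had 78.0 ± 3.49 against 101 ± 6.15. Genes with the smallest p among those higher in Tshr-/- did not pass either. Cirbp, a cold-inducible RNA-binding protein, had 28.6 ± 2.66 FPKM against 20.8 ± 0.724. Col23a1, a membrane collagen, had 1.77 ± 0.552 against 0.586 ± 0.114. Gkn3, a gastrokine, had 3.80 ± 0.659 against 1.70 ± 0.376. AC154176.1, a processed pseudogene whose reads may come from its parent gene and which is therefore uncertain, had 25.0 ± 3.11 against 15.7 ± 1.82. These 7 genes each had a limma adjusted p of 0.0502. Each passed under some alternatives, 4 of 25 for AC154176.1 and from 5 to 7 of 26 for the others.

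Limma therefore called 2 of 15471 genes, 0 raised and 2 lowered, while 2015 had an unadjusted p below 0.05 (719 higher, 1296 lower) against 774 that unchanged genes would give on average. Of 100 splits of the libraries, described below and with the real split included, 9 gave as many. The excess is therefore not tied to genotype. Limma voom on the rebuilt reads called 2 genes, Penk and Cyp26b1, and likewise 0 raised. Penk lost its call without Tshr-/- library 2 or wild-type library 2, 3 or 4 (log2 differences from -0.868 to -0.837, adjusted p = 0.0503, 0.0732, 0.081 and 0.0601) and with covariates for thalamus, choroid plexus and neocortex (log2 difference -0.69, 0.0706). Cyp26b1 lost it without Tshr-/- library 1, 2 or 3 (0.0681, 0.0845 and 0.0625) or any 1 wild-type library (0.0523 to 0.116), with log2 differences from -1.56 to -1.41 in these 8 fits, and also with no variance trend (0.0739) and among the 6 libraries low in thalamic markers (0.161), and its log2 difference stayed at -1.49 and -1.51 in the last 2. The count of called genes rose to 13 with a filter at 1 FPKM and to 17 among protein-coding genes.

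**Figure D1:**
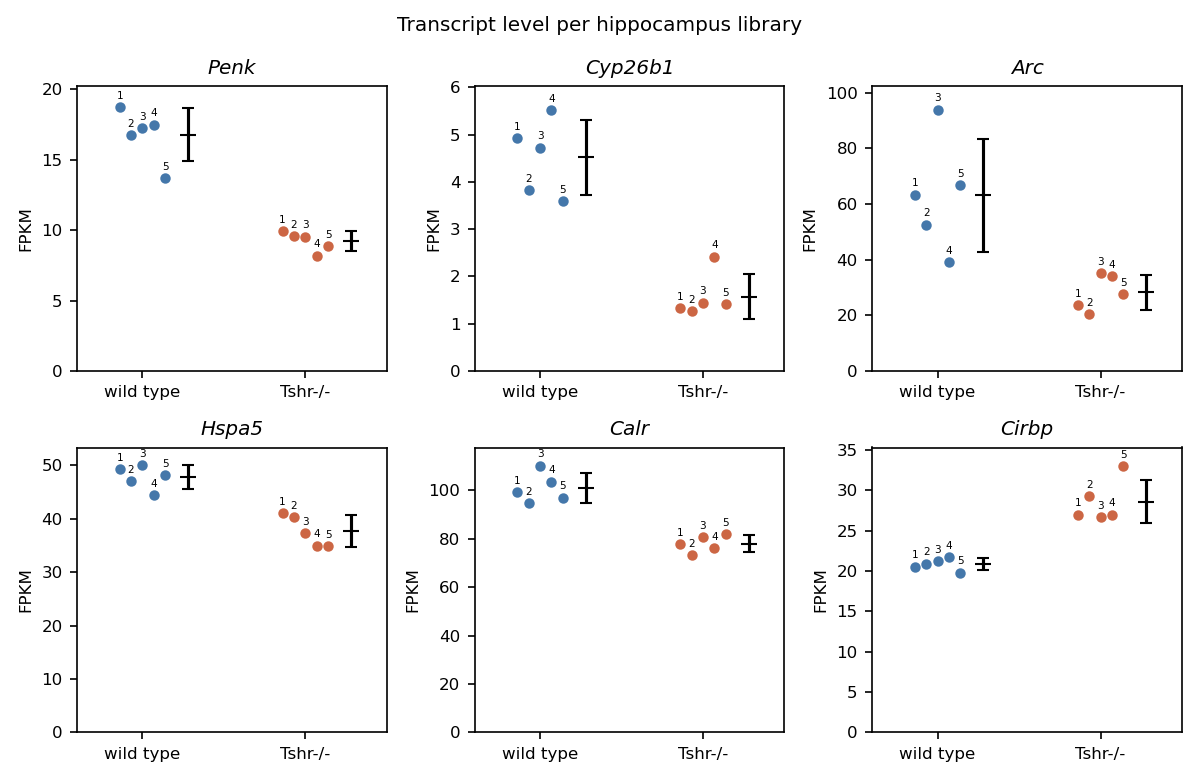
FPKM of 6 genes in each library, wild type in blue and Tshr-/- in orange, with replicate numbers beside the points and bars for the mean ± SD of 5 libraries. Penk, Cyp26b1, Arc, Hspa5 and Calr lie lower in each Tshr-/- library than in each wild-type library and Cirbp lies higher, and of these only Penk (adjusted p = 0.0127) and Cyp26b1 (0.0319) passed the limma test.

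Groups of genes were compared next. Of 42 lists, camera called 14, with 6 lower and 8 higher in Tshr-/-. The activity-regulated immediate early genes, which neurons induce within minutes of firing, were lower for all 22 members (camera adjusted p = 6.97e-14, mean log2 difference -0.57). With an estimated correlation (0.349 between its genes) the adjusted p of this list was 0.337. Of the 22, 17 fell when adjusted over the list alone and 0 when adjusted over all genes. Arc, which acts on AMPA receptor uptake at synapses, fell from 63.1 ± 20.3 to 28.2 ± 6.44 FPKM (log2 -1.13). Fos fell from 5.88 ± 1.69 to 2.99 ± 0.319 FPKM, Fosb from 1.96 ± 0.492 to 0.997 ± 0.198, and Dusp6, a phosphatase of the ERK pathway, from 24.7 ± 2.12 to 16.6 ± 2.74. All 4 had a limma adjusted p of 0.00319 over the list alone.

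The heat shock and unfolded protein response list was lower in Tshr-/- for 18 of its 20 genes (camera adjusted p = 1.48e-10, 0.143 with an estimated correlation, mean log2 difference -0.24). Of these, 14 fell when adjusted over the list alone and 0 over all genes. They include proteins of the endoplasmic reticulum, among them Calr (log2 -0.37), Hspa5 (BiP, from 47.8 ± 2.18 to 37.7 ± 2.93 FPKM, log2 -0.34) and Creld2 (from 10.1 ± 0.397 to 8.19 ± 0.442, log2 -0.30). They also include the cytosolic chaperone Hsph1 (from 43.3 ± 1.21 to 35.6 ± 2.50, log2 -0.28). Their adjusted p values over the list alone were 0.000606, 0.000998, 0.000998 and 0.00144. For both lists the mean per library was lower in each Tshr-/- library than in each wild-type library, with an exact permutation p of 0.00794, the smallest that 5 against 5 allow. Adjusted over all 42 lists these p values were 0.0833. The voltage-gated potassium channel and neurotrophin lists, described below, were likewise lower in each Tshr-/- library than in each wild-type library. Their exact permutation p values were the same, so complete separation was not limited to the immediate early and heat shock lists.

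**Figure D2:**
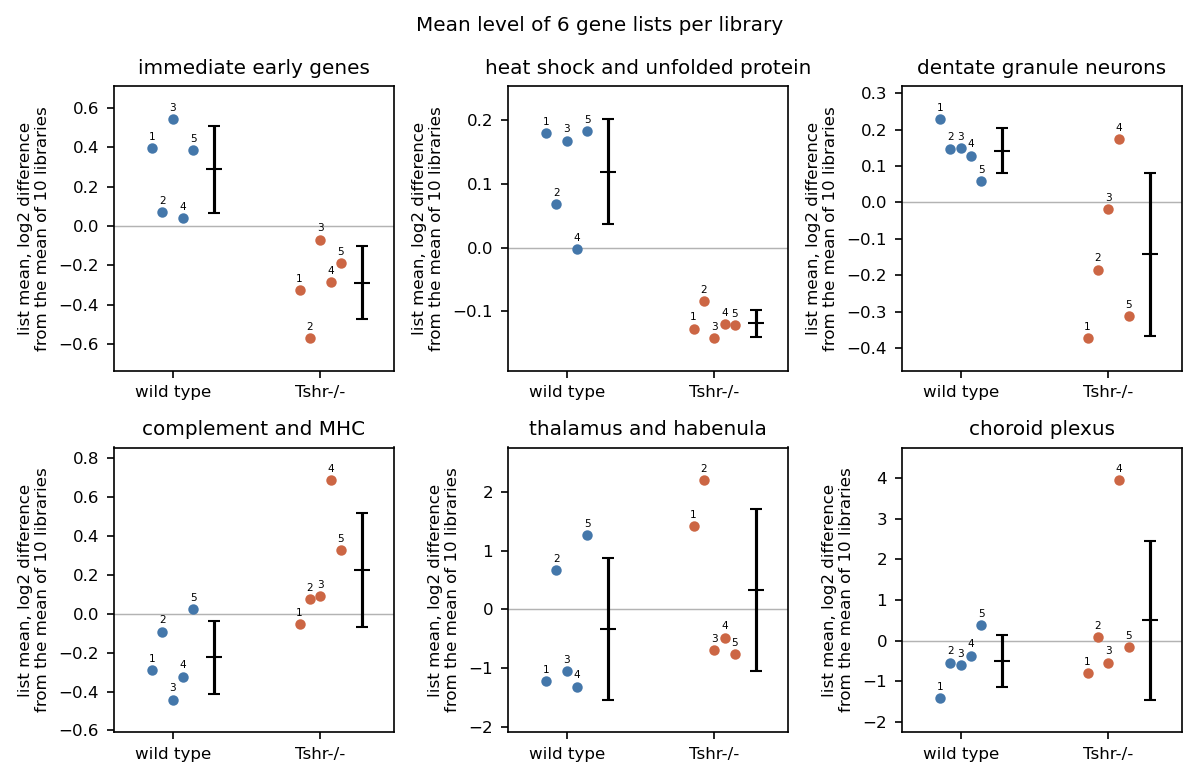
Mean log2(FPKM + 0.1) of 6 gene lists in each library, as the difference from the mean of all 10 libraries, with replicate numbers beside the points and bars for the mean ± SD of 5 libraries. The immediate early and the heat shock and unfolded protein lists separate the genotypes completely, the thalamus list is high in Tshr-/- libraries 1 and 2 and wild-type libraries 2 and 5, and the choroid plexus list is high in Tshr-/- library 4.

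Markers of dentate granule and CA1 neurons were also lower, while those of CA3 and CA2 neurons were higher for 8 genes and lower for 7, with a mean log2 difference of 0.12, and were not called (camera adjusted p = 0.226). The dentate gyrus granule neuron list was lower for 11 of 12 genes (camera adjusted p = 2.77e-05, 0.397 with an estimated correlation), and 7 fell when adjusted over the list alone, 0 over all genes. C1ql2, a secreted synaptic protein of mossy fibres, fell from 77.8 ± 16.2 to 44.4 ± 12.2 FPKM (log2 -0.83). Sipa1l2 fell by 0.28, Dock10 by 0.29 and Trpc6, a cation channel, by 0.51 on the log2 scale, each with an adjusted p over the list alone from 0.0103 to 0.0137. The CA1 pyramidal neuron list was lower for 8 of 10 genes (camera adjusted p = 0.00359, 0.566 with an estimated correlation), and 4 fell when adjusted over the list alone, 0 over all genes. These were Lefty1 (from 10.9 ± 1.98 to 6.5 ± 1.21 FPKM), Fibcd1 (43.7 ± 7.95 to 26.9 ± 7.68), Gpr161 (16.1 ± 1.76 to 11.4 ± 2.32) and Pou3f1 (43.9 ± 11.1 to 25.9 ± 8.09). The library means of these 2 lists overlapped between the genotypes. The dentate mean of Tshr-/- library 4 lay above 4 of the 5 wild-type libraries (exact permutation p = 0.0397, 0.208 adjusted over all lists), and the CA1 means of Tshr-/- libraries 3 and 5 lay above wild-type libraries 2, 4 and 5 (0.103, 0.31 adjusted). Thalamic markers were highest in Tshr-/- libraries 1 and 2. Among the 6 libraries low in thalamic markers, camera at the preset correlation again called both lists lower. This subset did not remove the thalamic difference. Relative to the mean of all libraries, its thalamus list lay from -0.77 to -0.48 in Tshr-/- and from -1.32 to -1.05 in wild type. The dentate and CA1 library means still overlapped between the genotypes there, so the subset does not decide whether thalamic tissue bears on these lists.

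Synaptic receptor and channel lists moved by less. The list of AMPA, NMDA and kainate receptor subunits and postsynaptic scaffolds was lower for 24 of 31 measured genes (Dlg2 has 2 gene records), with a camera adjusted p of 0.00359, and 0.566 with an estimated correlation. Of these, 3 fell when adjusted over the list alone, 0 over all genes, namely Homer1 (log2 -0.44), the scaffold Shank3 (-0.31) and the NMDA receptor subunit Grin2a (-0.39). Homer1 is also in the immediate early list. Gria1 had 154 ± 24.3 FPKM against 191 ± 16.5 (adjusted p over the list alone 0.0597). Voltage-gated potassium channel genes were lower for 13 of 19 (camera adjusted p = 0.022, 0.411 with an estimated correlation), and 6 fell when adjusted over the list alone, 0 over all genes. Kcnab2 fell from 173 ± 15.7 to 127 ± 19.9 FPKM and Kcnab1 from 16.8 ± 1.59 to 13.7 ± 1.13. The potassium channel call ended with quantile normalization (adjusted p = 0.149), without Tshr-/- library 4 (0.111) or wild-type library 5 (0.0787), among the libraries low in thalamic markers (0.082) and after the GC and length correction (0.053). Its mean log2 difference of -0.114 was then -0.0672, -0.0839, -0.104, -0.105 and -0.110.

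Lists that stood higher in Tshr-/- were of immune, lipid and tissue border genes. The complement and MHC list was higher for 14 of 18 genes (camera adjusted p = 8.53e-05, 0.566 with an estimated correlation). The 4 genes that rose when adjusted over the list alone (0 over all genes) all belong to MHC class II antigen presentation. H2-Ab1 rose from 0.464 ± 0.119 to 1.75 ± 0.769 FPKM, H2-Aa from 0.189 ± 0.168 to 0.843 ± 0.516, H2-Eb1 from 0.962 ± 0.488 to 2.25 ± 1.15 and their invariant chain Cd74 from 0.797 ± 0.523 to 2.53 ± 1.63. All 15 measured interferon-stimulated genes were higher (camera adjusted p = 0.00024, 0.566 with an estimated correlation), and none passed when adjusted over the list alone or over all genes. Limma gave 4 of them an unadjusted p below 0.05, with Ifit3 at 2.73 ± 0.334 against 1.97 ± 0.405 FPKM, Ifit1 at 0.872 ± 0.193 against 0.520 ± 0.149, Lgals3bp at 5.44 ± 2.38 against 3.47 ± 0.366 and Irf7 at 0.803 ± 0.348 against 0.457 ± 0.0714. Limma voom also called none of the 4. The means of both immune lists were highest in Tshr-/- library 4, the library high in choroid plexus transcripts. Camera at the preset correlation still called both lists without that library. Both calls ended with covariates for thalamus, choroid plexus and neocortex (camera adjusted p = 0.142 and 0.107).

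Cholesterol synthesis and uptake genes were higher for 18 of 21 (camera adjusted p = 0.000171, 0.559 with an estimated correlation). Of these, Nsdhl (5.56 ± 0.440 to 6.60 ± 0.265 FPKM) and Lss (2.83 ± 0.170 to 3.34 ± 0.148), both enzymes of the late pathway, rose when adjusted over the list alone, and 0 over all genes. Hmgcs1 had 40.2 ± 1.5 against 35.0 ± 4.10 FPKM and Mvk 10.1 ± 0.623 against 8.88 ± 1.01, and neither passed.

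Markers of tissue at or beyond the edge of the hippocampus, and of mossy cells and subiculum, were called higher by camera, with 0 genes past either adjustment. The meninges and fibroblast list was higher for 14 of 15 genes (adjusted p = 3.5e-05, 0.566 with an estimated correlation), with Slc22a6 at 0.870 ± 0.286 against 0.477 ± 0.225 FPKM, Col1a2 at 1.20 ± 0.470 against 0.662 ± 0.315, Slc13a4 at 2.01 ± 2.003 against 0.636 ± 0.438 and Fmod at 1.70 ± 0.683 against 0.944 ± 0.579. All 11 ependymal and ciliated cell genes were higher (0.000661, 0.566 with an estimated correlation), including the cilium genes Rsph1 (4.38 ± 2.08 against 2.17 ± 0.408 FPKM), Ak7 (0.904 ± 0.473 against 0.389 ± 0.207) and Dynlrb2 (2.20 ± 1.63 against 1.03 ± 0.575), and Rarres2 (1.66 ± 0.698 against 1.07 ± 0.248). The choroid plexus list had 12 of 13 higher (0.00806, 0.769 with an estimated correlation), among them Ttr, Otx2 (1.21 ± 1.40 against 0.306 ± 0.332), Cldn2 (1.18 ± 2.18 against 0.147 ± 0.108) and Kcne2 (2.50 ± 5.13 against 0.165 ± 0.146). The thalamus and habenula list had 15 of 15 higher (0.0101, 0.769 with an estimated correlation), among them Zic1, Zic4 (0.887 ± 0.646 against 0.282 ± 0.234), Calb2 (27.8 ± 23.6 against 12.4 ± 7.87) and Nwd2 (3.53 ± 1.47 against 2.58 ± 0.106). Mossy cell and subiculum genes were higher for 10 of 11 (0.0273, 0.566 with an estimated correlation), with Rprm at 28.1 ± 14.3 against 16.1 ± 1.20, Dlk1 at 1.10 ± 0.401 against 0.599 ± 0.308 and Calcrl at 1.39 ± 0.304 against 1.07 ± 0.168, while Ociad2 had 35.2 ± 2.73 against 40.4 ± 1.27. Limma gave 5 of the meninges, 2 of the ependymal, 0 of the choroid plexus, 1 of the thalamus and 2 of the mossy cell genes an unadjusted p below 0.05, and limma voom called none of the genes named here. The thalamus call ended without Tshr-/- library 1 or 2 or wild-type library 1 or 4 (camera adjusted p = 0.0761, 0.343, 0.0693 and 0.0752). Its mean log2 difference of 0.664 was then 0.393, 0.136, 0.442 and 0.418. The choroid plexus call ended with a filter at 1 FPKM or quantile normalization (0.0736 and 0.0596), where its mean of 1.01 was 0.988 and 0.822. Without Tshr-/- library 4 the 4 choroid plexus genes left by the filter were too few for camera. The ependymal call ended with covariates for thalamus, choroid plexus and neocortex (0.0923), where its mean of 0.573 was 0.334. The mossy cell call ended without Tshr-/- library 1 or 3 or wild-type library 4 (0.0615, 0.087 and 0.176) or with the thalamus covariate (0.0823). Its mean of 0.447 was then 0.379, 0.460, 0.238 and 0.267.

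Because Tshr acts through the thyroid, genes of thyroid hormone action were examined. The brain genes known to be induced by thyroid hormone were lower for 17 of 24 genes and the list was not called (camera adjusted p = 0.0803, 0.489 with an estimated correlation). Adjusted over the list alone, 5 fell and 2 rose, and 0 over all genes. Sema7a, a membrane semaphorin, fell from 75.2 ± 3.43 to 62.9 ± 4.32 FPKM, Bdnf from 8.42 ± 0.647 to 6.31 ± 0.956 and the small GTPase Rasd2 from 28.0 ± 4.15 to 19.8 ± 3.32, while the carbonyl reductase Cbr2 rose from 0.378 ± 0.115 to 0.823 ± 0.263. The direct targets Hr (3.68 ± 0.920 against 3.31 ± 0.645 FPKM, limma adjusted p = 0.812) and Klf9 (62.4 ± 6.12 against 63.2 ± 6.27, 0.949) did not pass, nor did Dio3 (0.869 ± 0.425 against 1.11 ± 0.427, 0.72), Nrgn (1100 ± 257 against 1340 ± 163, 0.438) or Mbp (289 ± 62.1 against 324 ± 66.7, 0.722). The sign of Klf9 turned with quantile normalization (0.07), and that of Hr with tissue covariates (-0.28). The thyroid-induced list was called lower under 9 of 29 alternatives, with adjusted p values from 0.000708 to 0.489 over all of them.

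In the list of thyroid hormone transport, deiodination and receptors (camera adjusted p = 0.49), 1 of 19 genes fell when adjusted over the list alone and 0 over all genes. The mean of this list was 0.03, its median -0.07 and its camera direction lower. Its mean includes Ttr, which had a log2 difference of 2.17 and reached 2189 FPKM in Tshr-/- library 4, the library high in choroid plexus transcripts. Iyd, which recovers iodide from iodotyrosines and in the hippocampus also marks CA3 neurons, fell from 2.99 ± 0.292 to 1.5 ± 0.453 FPKM (log2 -1.01, adjusted p over the list alone 0.0086). Dio2, the enzyme that makes active thyroid hormone, had 6.46 ± 0.874 FPKM against 7.65 ± 0.188 (limma adjusted p = 0.278, 0.135 over the list alone). The coactivator Ncoa1 had 19.9 ± 1.11 against 21.6 ± 0.888 and did not pass. The list of the TSH receptor, its ligands and G protein and cAMP signalling was not called (camera adjusted p = 0.448), with 0 of 29 genes past either adjustment and 7 at an unadjusted p below 0.05 in limma. Its leading members were the G protein genes Gnas (12.2 ± 0.649 against 14.8 ± 1.51 FPKM), Gna12 (24.9 ± 1.57 against 29.97 ± 3.31) and Gnaq (45.9 ± 3.09 against 51.4 ± 2.29) and the cAMP-responsive factor Crem (2.27 ± 0.179 against 2.63 ± 0.0963), each with an adjusted p over the list alone of 0.0992. Limma voom also called none of them.

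Among neurotrophins and their receptors (camera adjusted p = 0.132) 3 of 13 genes fell when adjusted over the list alone and 0 over all genes. Among them were Bdnf, as given, and the secreted neuropeptide precursor Vgf, which fell from 259 ± 34.9 to 192 ± 26.4 FPKM, while the receptor Ntrk2 had 30.1 ± 2.08 against 28.6 ± 1.17 and did not pass. The core clock genes, which peak at opposite times of day, were not called as a list (camera adjusted p = 0.999). Camera looks for a shift of the list to a single side, so it could hardly call genes of opposite phase. For change in either direction the fry adjusted p of this list was 0.000447. Adjusted over the list alone, 3 fell and 2 rose, and 0 over all genes. Arntl fell from 4.27 ± 0.232 to 3.51 ± 0.185 FPKM and Nfil3 from 6.02 ± 0.768 to 4.41 ± 0.387, while Ciart rose from 2.86 ± 0.451 to 4.63 ± 1.15 and Dbp from 14.5 ± 2.16 to 19.5 ± 3.01.

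No other list was called by camera. Among cell type lists the adjusted p was 0.0999 for inhibitory interneurons, 0.11 for pan-neuronal markers, 0.179 for oligodendrocyte precursor cells, 0.226 for CA3 and CA2 neurons, 0.619 for myelin, 0.84 for microglia, 0.912 for vascular cells, 0.912 for adult neurogenesis and 0.999 for astrocytes. Among synaptic lists it was 0.179 for voltage-gated calcium and sodium channels, 0.532 for metabotropic glutamate receptors, 0.532 for presynaptic proteins, 0.912 for monoamine and acetylcholine receptors and 0.956 for GABA receptors and synthesis. Glucocorticoid-induced genes (0.14), cytosolic ribosomal proteins (0.14), nuclear (0.27) and mitochondrial (0.532) respiratory chain genes, amyloid and tau genes (0.331), ERK and AKT-mTOR kinases (0.448), neocortex (0.411), striatum (0.912) and red blood cell genes (0.448) were not called either. With an estimated correlation camera called 0 of the 42 lists, 4 of them at an unadjusted p below 0.05. Fry called 4 lists lower, those of heat shock and unfolded protein (0.00504), immediate early (0.0245), neurotrophin (0.0245) and dentate granule neuron genes (0.0383). For change in either direction, again without comparison to other genes, fry called 16 lists.

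Genes near Tshr can carry alleles of the strain in which a mutation was made, so its neighbours on chromosome 12 were compared. None of the 119 tested genes within 10 Mb of Tshr was called by limma, which decides little where 2 were called in all (Fisher's exact p = 1). Of the 119, 16 had an unadjusted p below 0.05, about the share in the rest of the genome (Fisher's exact p = 0.891). Limma voom likewise called 0. Fos of the immediate early list also lies in this window (85473890 to 85477273, log2 -0.91 ± 0.19 SE, limma adjusted p = 0.136), so linked alleles may bear on it too. The nearest tested genes before Tshr were Dio2 (90724552 to 90738438, log2 -0.25 ± 0.09 SE), Nrxn3 (88722876 to 90334935, -0.10 ± 0.05) and Adck1 (88360554 to 88461724, -0.02 ± 0.08). Those after it were Gtf2a1 (91555262 to 91590487, -0.15 ± 0.06), the small nucleolar RNA Gm25776 (91573430 to 91573572, 0.50 ± 0.68) and Ston2 (91633009 to 91788387, -0.13 ± 0.09). Gm25776 lies within Gtf2a1, and reads of the 2 genes may be shared. The count within 10 Mb was 1 among protein-coding genes alone, 1 after the GC and length correction and 1 without Tshr-/- library 3.

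**Figure D3:**
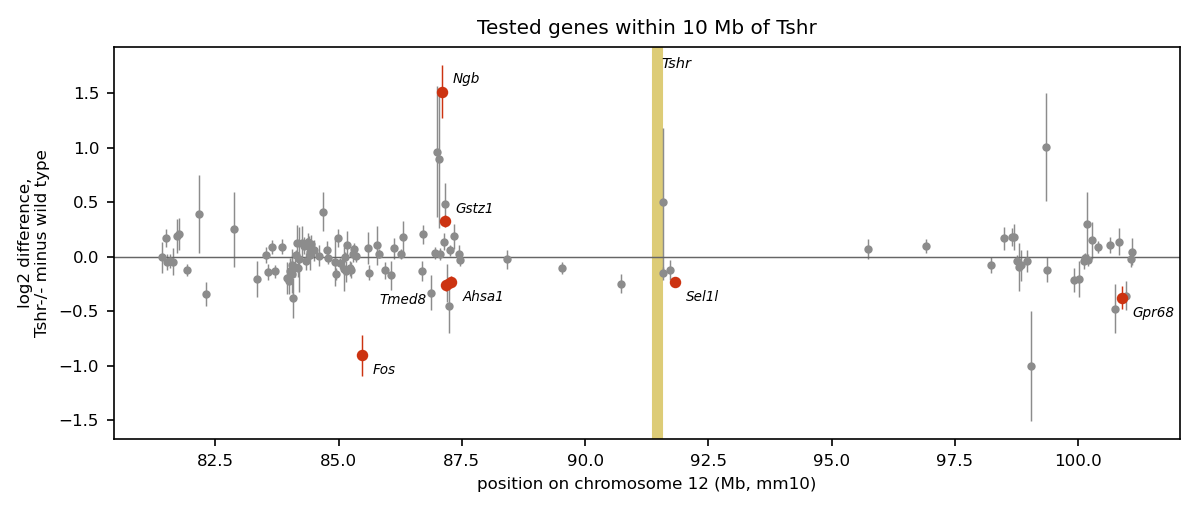
Log2 difference between Tshr-/- and wild type, with SE bars, for the 119 tested genes within 10 Mb of Tshr against their position on chromosome 12, with the 7 genes at an unadjusted p below 0.01 in red and Tshr as a yellow band. None of the genes passed the limma test over all genes, and Ngb has the largest difference among the red genes, 1.51.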

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

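Among 260 groups of 5 values, those of each named gene and described list in each genotype, 17 had 1 library far from the other 4 by Dixon's criterion, where chance gives about 1 in 20. In Tshr-/- library 4 these were Cyp26b1 (gap over range 0.806, at 2.41 FPKM against 1.27 to 1.44), Klf9 (0.777, lowest at 51.8), Cldn2 (0.822), Kcne2 (0.829), Slc13a4 (0.889), the choroid plexus list (0.814) and, as the lowest, the core clock list (0.724). In wild-type library 4 they were Rprm (0.718), Gpr17 (0.801), the adult neurogenesis list (0.758) and the monoamine and acetylcholine receptor list (0.864). In Tshr-/- library 5 they were Gkn3 (0.798, lowest at 2.66 FPKM) and Iyd (0.733, lowest at 0.757). The others were Fibcd1 in Tshr-/- library 3 (0.771, highest at 40.4 FPKM), Bdnf (0.773, lowest at 7.29) and Gad1 (0.817) in wild-type library 2, and Adck1 in wild-type library 5 (0.825, lowest at 4.63).

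Other splits of the 10 libraries into 5 and 5 were drawn, 100 of the 126 possible ones with the real split included. As many genes as the 2 called were reached by 3 of the 100 splits, and as many as the 2 lowered by 3, under the 5% set beforehand. Both counts are of the same genes, Penk and Cyp26b1, and the share was not adjusted for the other counts tried. Without Tshr-/- library 2 or wild-type library 2, 3 or 4, 0 genes were called. Chance is therefore not firmly excluded for these counts. The 0 genes raised were reached by all 100. The highest other split called 683 genes, with at most 433 in 1 direction. It set Tshr-/- libraries 1, 2 and 4 and wild-type libraries 2 and 5 against the rest, which includes the 4 libraries highest in thalamic markers, and so points to a structure of the samples other than genotype. The 14 lists called were reached by 28 splits (highest other 22), and the 2015 genes at an unadjusted p below 0.05 by 9 splits (highest other 3743), so that chance is not excluded for either.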

How the results depend on the processing

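The count of 2 called genes changed under many of the alternatives. The genes called (raised and lowered) stayed at 2 (0 and 2) with median-ratio scaling, array quality weights and limma voom, and numbered 3 (0 and 3) with pseudocount 1, 14 (8 and 6) with pseudocount 0.01, 4 (0 and 4) with no filter, 13 (7 and 6) with a filter at 1 FPKM, 4 (2 and 2) with quantile normalization, 1 (0 and 1) with no variance trend, 13 (7 and 6) with robust empirical Bayes and 17 (8 and 9) among protein-coding genes, where 1 lay within 10 Mb of Tshr. Leaving out 1 library gave 0 to 9 called genes, 0 to 4 raised, 0 to 5 lowered, 0 to 1 within 10 Mb of Tshr and 13 to 17 lists. Of alternatives chosen after seeing the data, the thalamus covariate gave 8 (1 and 7), tissue covariates 1 (0 and 1), the libraries low in thalamic markers 3 (1 and 2), and the GC and length correction 16 (6 and 10), 1 of them within 10 Mb. Penk passed in 21 of its 26 alternatives and Cyp26b1 in 16 of 26, both lower in all. The 14 lists were 0 with an estimated correlation, 4 with fry and 0 by exact permutation of list means, whose smallest p does not pass over 42 lists, and 13 to 17 under the other alternatives except 20 with no filter. No called list but that of choroid plexus turned its direction. The choroid plexus difference ran from -0.0323 to 1.35 with 1 library left out. It turned sign without Tshr-/- library 4, where 4 of its genes passed the filter, and over the same 13 genes, an alternative chosen after seeing the data, it was 0.149 there. The Tshr difference ran from -0.0345 to -0.023 FPKM with 1 library left out. Genes that did not pass turned sign as follows: Adck1 with the thalamus covariate (0.021) and tissue covariates (0.13), Hr (-0.28) and Otx2 (-0.0414) with tissue covariates, Klf9 with quantile normalization (0.0664), and with 1 library left out Adck1 (-0.0888 to 0.0187), Gm25776 (-0.0609 to 0.842) and Klf9 (-0.0608 to 0.0475). The cause was not tested for any of these. Same-numbered libraries did not deviate together (correlations from -0.0651 to 0.296, and 2 of 5 Tshr-/- libraries closest to their own number). The replicate block gave 3 called genes, 0 raised and 3 lowered, and 16 lists. It called the thyroid-induced (0.0268) and interneuron (0.0432) lists. No pseudocount, trend or weight alternative applies to the FPKM of Tshr, nor do trend, robust or weight settings to the choroid plexus mean. The simulated libraries gave 36.7% of 1.3-fold changes and 88% of 2-fold changes as called. These shares may be too high for the real libraries. The simulated genes varied independently, and with 140 genes called the adjusted threshold was looser than with 2. At this depth a Tshr level below 0.0148 to 0.0217 FPKM, 3 reads per library, was not measurable.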

Other observations

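Several lists that camera did not call held members that passed when adjusted over the list alone, with 0 of those named next called over all genes except Penk. Among inhibitory interneuron genes 2 of 17 fell, Npy (81.4 ± 6.20 to 54.0 ± 15.6 FPKM) and Gad1 (37.5 ± 2.37 to 32.7 ± 1.5), while Pvalb (28.9 ± 6.95 against 41.1 ± 9.29) and Sst (289 ± 87.4 against 357 ± 31.5) did not pass. In the adult neurogenesis list Nes fell from 2.31 ± 0.256 to 1.64 ± 0.273 FPKM and Prox1 from 14.9 ± 1.42 to 11.8 ± 1.78, Dcx rose from 1.04 ± 0.141 to 1.55 ± 0.247, and Neurod2 had 96.6 ± 24.8 against 127 ± 23.5. Among monoamine and acetylcholine receptors Htr2c rose from 2.57 ± 0.835 to 5.27 ± 1.55 FPKM, Htr1a fell from 10.8 ± 1.3 to 8.06 ± 1.47 and Drd5 from 2.78 ± 0.369 to 1.97 ± 0.426, and Drd1 had 1.49 ± 0.528 against 0.895 ± 0.183. Of the oligodendrocyte precursor genes, Gpr17 fell from 10.2 ± 0.852 to 8.48 ± 0.384 FPKM and C1ql1 from 7.68 ± 0.936 to 6.05 ± 0.707, while Sox10 (23.7 ± 4.32 against 31.2 ± 5.63) and Tnr (18.7 ± 0.685 against 20.3 ± 0.783) did not pass. In the striatum list Penk and Rasd2 fell.

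All tests in the next paragraphs were chosen after the results of the main comparison were seen, and those of the clock score and of the share of genes around Tshr also after their own values were known. Chosen after the results were seen were also Sel1l, Ngb, Gstz1, Tmed8, Ahsa1, Mrc1 and H2-DMa as genes to name, and the covariates and the GC and length correction as alternatives. The 42 genes of the immediate early and the heat shock and unfolded protein lists had a median log2 difference of -0.37. It was -0.357 after the correction for GC content and gene length and -0.339 with covariates for thalamus, choroid plexus and neocortex. Meninges, ependymal cells and hippocampal subfields were not among the covariates. That the median shifted so little argues only against GC content, gene length or the tissues adjusted for as the whole cause. The permutation p of the mean of the 42 genes was 0.00794 in each case, but it adds nothing to this. These lists were taken up after each was seen to separate the genotypes completely, and the p restates that choice. A lower tissue temperature in Tshr-/- mice was considered as a cause. Heat shock factor targets outside the fixed lists were lower by 0.14 (-0.139, exact permutation p = 0.0238). They share a regulator with heat shock genes already seen to be lower. Their fall therefore does not separate temperature from other causes of that pattern. A different time of day or state of the mice at collection was considered as well. The score of clock genes high after dusk minus those in the opposite phase was 0.282 higher (exact permutation p = 0.0238). That test asked only whether the score differed. It does not show whether such a shift would lower or raise the 42 genes. Both stay open beside an effect of the genotype on neuronal activity or thyroid state, which was not tested because the labels give no time, temperature or hormone level.

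The 4 MHC class II genes were set apart because they passed in their list, and a p of their mean would only restate that choice. The mean was 1.53 higher in Tshr-/- on the log2 scale and 1.27 higher without Tshr-/- library 4. Border tissue in some libraries stays open as a cause. With the meninges and choroid plexus list means as covariates the mean was 0.983 higher, but it rests on genes chosen for their difference. The 6 measured MHC class II genes outside the fixed list were on average 0.183 higher (exact permutation p = 0.135) and with these covariates 0.157 (permutation p = 0.31), which decides nothing. Of these, H2-DMa had the highest level and was lower in Tshr-/-, at 7.08 against 8.12 FPKM. The others had higher means in Tshr-/- but lay below 1 FPKM in both genotypes. More macrophages of the brain borders are a candidate explanation: their markers outside MHC class II were 0.73 higher (exact permutation p = 0.0238), with Mrc1 at 0.577 ± 0.287 against 0.173 ± 0.124 FPKM, and 0.659 higher without Tshr-/- library 4 (exact permutation p = 0.0556). In Tshr-/- library 5, second highest in MHC class II genes, these markers lay within the wild-type range. Of the 9 measured markers, 8 were below 1 FPKM in both genotypes. Whether such cells were more numerous in the tissue or were left on it at dissection stays open.

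Between 4.11 and 4.29 Mb before Tshr, 4 genes within 0.176 Mb had small p values. Ngb (neuroglobin, 87097531 to 87102539) had 2.54 ± 0.692 FPKM against 0.821 ± 0.277 and Gstz1 (87147165 to 87164723) 6.53 ± 0.129 against 5.2 ± 0.360, while Tmed8 (6.58 ± 0.292 against 7.91 ± 0.486) and the Hsp90 cochaperone Ahsa1 (19.1 ± 0.835 against 22.5 ± 1.51) were lower, with limma adjusted p values of 0.0603, 0.0709, 0.143 and 0.173. Sel1l, 0.256 Mb after Tshr and a part of protein degradation at the endoplasmic reticulum, whose chaperones were also lower, had 18.0 ± 0.902 against 21.2 ± 0.71 (0.136). Alleles of another strain linked to the mutation may underlie these differences, and 0 other chromosomes had a window of 7 neighbouring tested genes with 4 or more at p below 0.002. The windows at Ngb held 3 such genes, as did windows around Arc on chromosome 15, so the criterion of 4 was not met there either and the test decides nothing. Over the whole 10 Mb on both sides the share of genes at p below 0.01 was 5.88% against 3.99% elsewhere (Fisher's exact p = 0.34), which leaves linked alleles and chance impossible to separate without genotypes of the mice.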
